A study of Mus musculus with 6 samples.

How the data were processed

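The series profiled protein occupancy on chromatin by ChIP-seq (chromatin immunoprecipitation followed by sequencing) in 2 mouse cell types. The macrophages were primary cells washed from the peritoneum of male C57BL/6 mice 3 days after injection of 1 ml of sterile 3% thioglycollate, which draws inflammatory cells into the cavity, and collected after 24 h of adherence. The adipocytes were differentiated 3T3-L1 cells, a mouse fibroblast-derived preadipocyte line. Per the labels' protocols, macrophages from at least 4 animals were pooled for each sequencing run, the macrophage PPARγ data joined 2 runs, and each other library came from 1 run. Reads of 36 bp were mapped by the authors to the mouse genome build mm8 with ELAND, allowing up to 2 mismatches and keeping reads with a unique best match, per the labels' protocols. The version of the aligner, the settings of the peak caller and the control library are not given in the sources used here. All reads that map equally well to several places were left out by that rule, so repeated sequence is under-represented in every list.

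The deposited files are lists of called regions: a main list for each library, a longer list for macrophage PPARγ, a longer adipocyte PPARγ list described as combining 3 datasets, and a file of masked intervals. Libraries were grouped by their titles, which name the same targets as the antibody field of the records, while the description field names PPARγ for all 6, including those taken here as libraries of other targets. Each group holds 1 library, so no measurement has replicates, and the tests run over the regions of the lists: they compare these lists, not replicated cell populations. The final PPARγ lists and the longer macrophage list carry, per the file headers, a fold per region, which the peak caller gave relative to a control that the files do not name. They also carry a peak height, a signal in whole units per the file headers, with no scaling for depth stated. A false discovery rate per region is deposited as well and was read as a percent, because values in the longer macrophage list exceed 1. These values are the authors' own, and they were used only to rank, split or describe regions within a list. The lists for PU.1, C/EBPβ and acetylated histone H3 lysine 9 (H3K9Ace) give positions alone. All H3K9Ace regions start on a 50-bp grid, against 2.00% of PU.1 regions, and are at least 500 bp wide. The total number of reads per library is not in these files, so the sequencing depth is unknown.

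The series design text says that areas of input bias were subtracted before the final lists were made. The 460 deposited masked intervals include 238 on chromosome 10 and 130 on chromosome 2, and no region of a final list overlapped any of them. A longer macrophage PPARγ list with 18470 regions was also deposited. Taking its regions with a fold of at least 5 and the lowest false discovery rate, 0.24%, gave 1991 regions, 30 of them overlapped a masked interval, and the other 1961 were exactly the final macrophage list. The final adipocyte list has the same lowest fold, 5, and a false discovery rate of 0.34% in every row. An adipocyte list described as combining 3 datasets, with 12430 regions and no fold, peak height or false discovery rate, was used in alternatives only. The adipocyte H3K9Ace list held 20 repeated rows, which were counted once.

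Regions were compared by overlap of at least 1 bp. Macrophage PPARγ regions overlapping an adipocyte PPARγ region were called shared, and the rest of each list macrophage-only or adipocyte-only. The shared class is counted in macrophage regions, except where the adipocyte list itself is described. Shares carry 95% Wilson intervals, which cover counting error only and treat regions as independent. Overlaps of lists were set against 1000 circular shifts of the list within each chromosome, as a 1-sided permutation test whose smallest p is 0.001. Shifted regions no longer lie in active chromatin more than elsewhere. An excess over the shifts therefore cannot tell joint binding from a common preference for such chromatin. The end of each chromosome was taken as the furthest region end in any list, since mm8 chromosome lengths were not used here. Classes were compared by 2-sided Fisher's exact tests, with sample odds ratios and exact conditional 95% intervals, and Benjamini-Hochberg adjustment over the 6 class tests of PU.1 and C/EBPβ and over the 6 class tests of H3K9Ace. Macrophage and adipocyte H3K9Ace at the same regions were compared by exact McNemar tests, 2-sided binomial tests on the regions marked in 1 cell type alone. Differences of median fold within a list were tested by 2-sided permutation with 100000 resamples, whose smallest p is 1e-05, adjusted over 6 comparisons. These tests, the classes and the rule for naming regions were fixed before the data were examined. The comparison of chromosomes (Fisher's exact tests with the same adjustment), the distances between centres, the view from the C/EBPβ side and the 1000 shifts for overlaps with the longer lists were added after seeing the data. The rule named in each class the 8 regions with the highest fold, taken for shared regions from the macrophage list.

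The overlap and test functions were tested on simulated data before use. A simulated list planted at 60.0% of macrophage-only and 5.58% of adipocyte-only regions was recovered at 60.3% and 6.45%, the second including chance overlaps with the simulated background, and the largest difference in any class was 0.868 percentage points over 4379 regions. In 200 further simulated comparisons, marks were drawn at random for each region at the same rate in macrophage-only and adipocyte-only regions, and 13 had an exact p under 0.05. These draws were independent between regions, so they do not cover dependence between neighbouring regions. Overlap counts of the macrophage PPARγ and PU.1 lists were equal to those of bedtools 2.31.1. The other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

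Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter region, region centres within 1000 bp, the upper 50% of each PPARγ list by fold, removal of masked regions, autosomes alone, the longer macrophage list, the combined adipocyte list, cell-type-only classes that avoid those lists too, PPARγ lists of equal length, shares of base pairs for H3K9Ace and mean log2 fold. Leaving out chromosome 6 was added after seeing the data. Alternatives used 100 shifts, except in those overlaps. Genes near the regions were not analysed here: the files pair no region with a gene, and the gene table at hand describes the later assembly GRCm38.p6, whose coordinates cannot be set beside mm8. Coordinates are given in mm8 as the lists give them, and whether a region lies in a gene, exon or intron is not stated for the same reason.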

Results

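The study mapped PPARγ, a ligand-activated nuclear receptor that drives fat cell differentiation and also acts in macrophages, in thioglycollate-elicited mouse peritoneal macrophages and in 3T3-L1 adipocytes. In macrophages it also mapped PU.1, an ETS-family factor of myeloid and B cells, and C/EBPβ, a leucine-zipper factor used by both lineages. H3K9Ace, a histone mark of active promoters and enhancers, was mapped in both cell types. Each of the 6 libraries is the only member of its group, so there are no replicates. The final PPARγ lists held 1961 regions in macrophages and 2634 in adipocytes, with median widths of 315 bp and 260 bp. The macrophage lists of PU.1 and C/EBPβ were far longer, with 46356 and 24421 regions. H3K9Ace covered 37263 regions and 53.1 Mb in macrophages, against 51257 regions and 100.1 Mb in adipocytes. Depth is unknown. The authors' peak height in the PPARγ lists was at least 9 in both, with medians of 13 in macrophages and 12 in adipocytes.

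The comparison of the PPARγ lists asks how far the receptor occupies the same positions in the different cell types. Most regions belonged to a single cell type. Of the macrophage regions, 214 of 1961 overlapped an adipocyte region, 10.9% (95% interval 9.61 to 12.4). From the adipocyte side, 216 of 2634 regions were shared, 8.20% (7.21 to 9.31). The shared part was nevertheless far above that of shifted positions: circular shifts gave a mean of 0.0692% of the macrophage list and at most 0.306%, permutation p = 0.001, the smallest the shifts can give. This left 1747 macrophage-only and 2418 adipocyte-only regions. The share rested on the lists used. Against the combined adipocyte list, whose regions are wider (median 899 bp) and cover 10.96 Mb against 0.752 Mb in the final list, 28.2% of the macrophage regions were shared, with 0.611% after shifting. Against the longer macrophage list 14.2% of the adipocyte regions were, with 0.397% after shifting (permutation p = 0.001 for each). With each longer list in place of its final list, the shared part of the longer list itself was 2.07% in macrophages and 4.33% in adipocytes.

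PPARγ regions were also spread differently over the chromosomes. Chromosome 6 held 375 of the adipocyte regions, 14.2%, and 136 of the macrophage regions, 6.94%, an odds ratio of 2.23 (95% interval 1.81 to 2.76) with an adjusted p of 9.76e-15 by Fisher's exact test over 19 autosomes and both marks. The excess was smaller in the combined adipocyte list, which had 1163 of its 12430 regions there, 9.36%. Adipocyte H3K9Ace regions lay on chromosome 6 more often too, 8.52% against 5.57% in macrophages. By the same tests chromosomes 5, 8, 15 and 19 were also over-represented in both the final PPARγ and the H3K9Ace list of adipocytes, and chromosomes 1, 10, 12, 14 and 16 under-represented. In the combined adipocyte list chromosomes 12, 14 and 16 held 3.56%, 3.51% and 3.98%, close to 3.47%, 3.62% and 4.03% of the macrophage PPARγ list. The shares of the other chromosomes named kept their direction there. The lowest odds ratios were those of chromosome 10, 0.552 for PPARγ and 0.667 for H3K9Ace. Chromosome Y held 14 macrophage PPARγ regions, all from 1292554 to 2630104, and the adipocyte lists had none there. None of the 14 overlapped PU.1 or C/EBPβ, against 78.3% of the other 1947 macrophage PPARγ regions. A Fisher's exact test of this, added after seeing the data, gave p = 6.12e-10, but it counts these neighbouring regions as independent. The PU.1 and C/EBPβ lists hold only 5 and 4 regions on the whole of chromosome Y, so little overlap was possible there. The missing overlap therefore cannot be read as a trait of these PPARγ regions. Whether these regions reflect PPARγ was not tested.

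**Figure D1:**
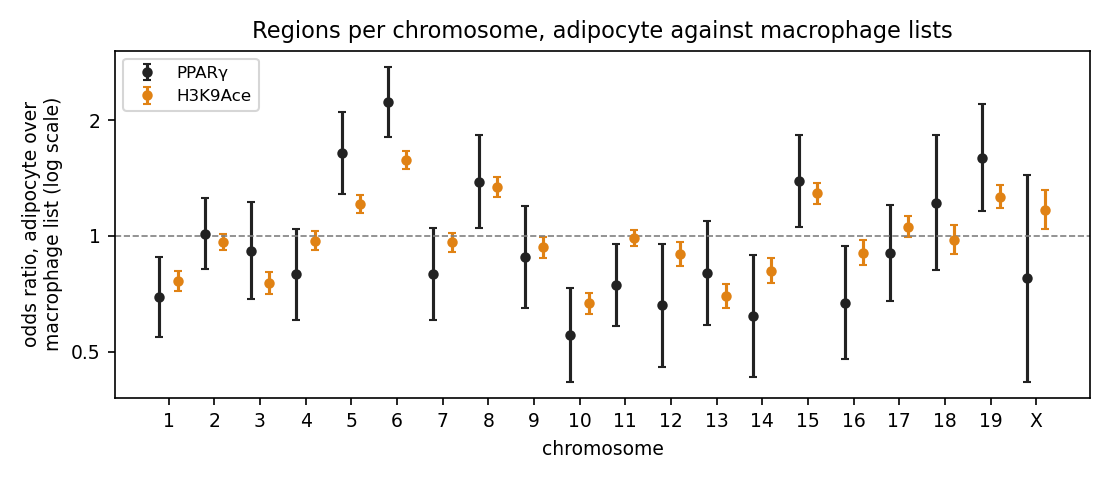
Odds ratio of lying on each chromosome for regions of the adipocyte list over regions of the macrophage list (log scale), for PPARγ and H3K9Ace, with exact 95% intervals. Chromosome 6 stands highest for both, at 2.23 and 1.58.

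Macrophage PU.1 was compared across the PPARγ classes to ask whether a myeloid factor accompanies PPARγ where the receptor binds in macrophages. PU.1 lay at 65.1% of macrophage-only regions (1137 of 1747, 62.8 to 67.3) and at 50.9% of shared regions (109 of 214, 44.3 to 57.6). At adipocyte-only regions it lay at 6.00% (145 of 2418, 5.12 to 7.01), which was above the 1.03% of shifted regions (permutation p = 0.001). The odds of PU.1 were 29.2 times higher at macrophage-only than at adipocyte-only regions (24.0 to 35.7), with an exact p too small for double precision. Shared regions exceeded adipocyte-only regions 16.3-fold in odds (11.7 to 22.6, Fisher's exact test, adjusted p = 9.38e-62). Macrophage-only regions in turn carried PU.1 more often than shared regions, with an odds ratio of 1.80 (1.33 to 2.41, Fisher's exact test, adjusted p = 6.4e-05). This last difference turned around with the longer macrophage list, to 0.559. It shrank to 1.26 with the combined adipocyte list (Fisher's exact test, unadjusted p = 0.0285). With the longer macrophage list the odds ratio of macrophage-only over adipocyte-only regions was 10.3. Against the combined adipocyte list that ratio was 15.5, and it was 44.4 when cell-type-only regions also had to avoid the longer lists.

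C/EBPβ also followed macrophage PPARγ, but was most frequent at shared regions. It lay at 58.1% of macrophage-only regions (1015 of 1747, 55.8 to 60.4), 73.4% of shared regions (157 of 214, 67.1 to 78.8) and 9.26% of adipocyte-only regions (224 of 2418, 8.17 to 10.5). Shifts of adipocyte-only regions gave 0.582%. Against adipocyte-only regions the odds ratio was 13.6 for macrophage-only regions (11.5 to 16.1, Fisher's exact test, adjusted p = 1.71e-262) and 27.0 for shared regions (19.1 to 38.3, adjusted p = 3.04e-96). Macrophage-only regions had lower odds of C/EBPβ than shared regions, with a ratio of 0.503 (0.360 to 0.697, Fisher's exact test, adjusted p = 1.48e-05). With the longer macrophage list the ratio of macrophage-only to adipocyte-only regions fell to 4.87 and that of macrophage-only to shared regions to 0.203. Taken as shared over macrophage-only regions the last ratio was 4.93, and it was lower within strata of height in that list, a test chosen after seeing the data, at 2.04 (1.63 to 2.56).

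**Figure D2:**
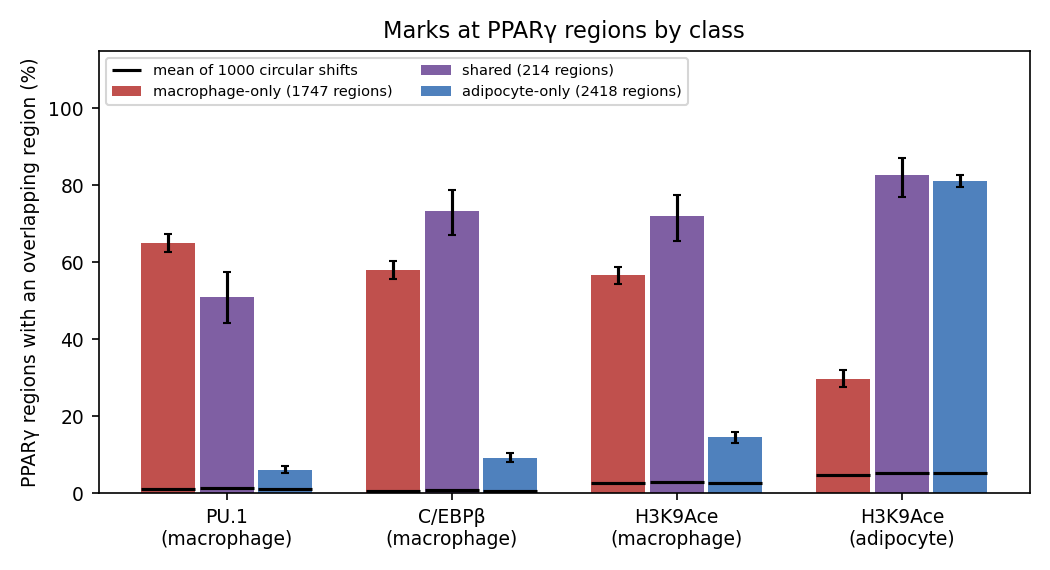
Percent of macrophage-only, shared and adipocyte-only PPARγ regions that overlap a region of each other list, with 95% Wilson intervals, and black lines for the mean of 1000 circular shifts. PU.1 falls from 65.1% to 50.9% and 6.00% across the classes, while adipocyte H3K9Ace lies at 29.7%, 82.7% and 81.1%.

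Both factors tended to mark the same PPARγ regions. Among macrophage-only regions, 799 had both PU.1 and C/EBPβ (45.7%, 43.4 to 48.1), where independent marks would give 660.6. PU.1 alone lay at 338 of these regions, C/EBPβ alone at 216, and 394 had neither (22.6%, 20.7 to 24.6). The odds ratio between the factors was 4.31 (3.48 to 5.34, Fisher's exact test, p = 4.68e-45). Shared regions had both factors in 94 of 214 cases and C/EBPβ alone in 63, but PU.1 alone in only 15, with an odds ratio of 4.18 (2.05 to 8.78, Fisher's exact test, p = 1.37e-05). Adipocyte-only regions lacked both macrophage factors in 2125 of 2418 cases (87.9%), and 76 had both where independence would give 13.4 (odds ratio 15.8, Fisher's exact test, p = 1.42e-44). The ratio among macrophage-only regions was 2.74 in the upper 50% of the lists by fold and 13.5 with the longer macrophage list.

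**Figure D3:**
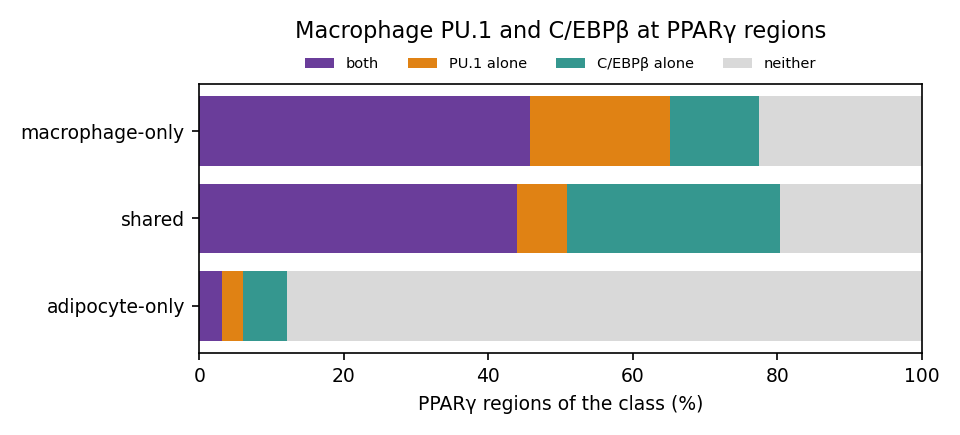
Percent of the PPARγ regions of each class that carry both macrophage PU.1 and C/EBPβ, a single factor or neither. Regions with C/EBPβ alone make up 29.4% of the shared class and 12.4% of the macrophage-only class, and regions with PU.1 alone 7.01% and 19.3%.

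Distances between centres were taken over all regions of a class, with or without the factor. Most macrophage-only and shared regions overlap each factor, so their short medians largely restate that overlap. The median distance between centres was 0.112 kb from macrophage-only regions to PU.1 and 0.138 kb to C/EBPβ. For shared regions these medians were 0.385 kb and 0.0955 kb. Adipocyte-only regions were further away, at a median of 11.3 kb from PU.1 and 20.3 kb from C/EBPβ, and 47.1% of them had a PU.1 centre within 10 kb. The distances were not set against shifted positions, so these values do not show nearness to either factor. The PU.1 list is also longer, with 46356 regions against 24421, which by itself brings its nearest centres closer.

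**Figure D4:**
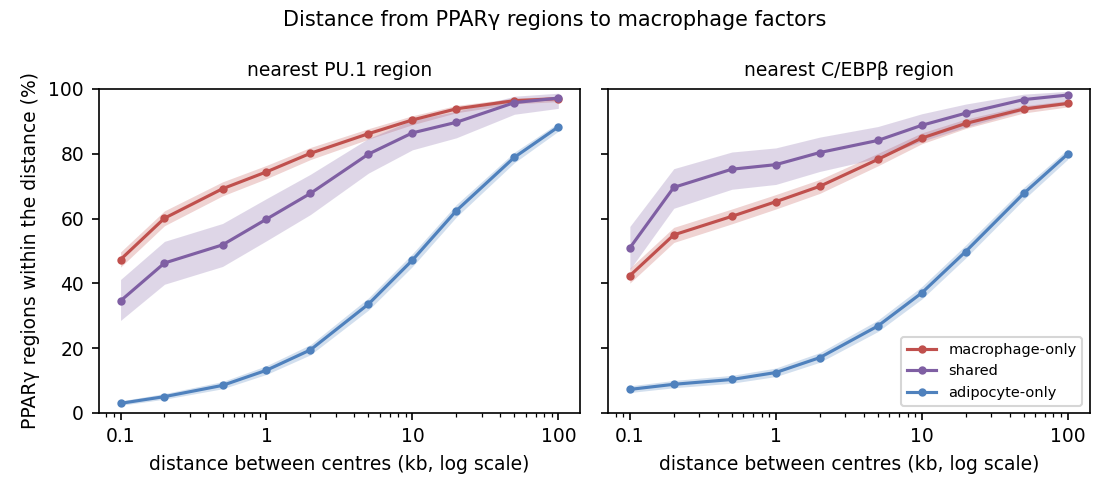
Percent of PPARγ regions of each class with a PU.1 centre (left) or C/EBPβ centre (right) within a given distance in kb (log scale), with 95% Wilson intervals as bands. At 0.2 kb the PU.1 curves stand at 60.1% for macrophage-only and 46.3% for shared regions, and the C/EBPβ curves at 55.0% and 69.6%.

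PU.1 and C/EBPβ met at many places without PPARγ as well. Over the genome, 53.2% of the C/EBPβ regions overlapped PU.1 (13001 of 24421, 52.6 to 53.9), against 1.06% after shifting (permutation p = 0.001). In the other direction 28.5% of PU.1 regions overlapped C/EBPβ (13224 of 46356, 28.1 to 28.9). PPARγ was present at 6.99% of PU.1 regions that also had C/EBPβ (924 of 13224) and at 1.11% of those without it (368 of 33132). The odds ratio was 6.69 (5.91 to 7.58, Fisher's exact test, p = 2.17e-231). From the C/EBPβ side, PPARγ lay at 6.96% of regions with PU.1 and 2.62% of regions without (odds ratio 2.78, 2.43 to 3.19, Fisher's exact test, p = 5.97e-58).

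H3K9Ace differed between the cell types over much of the genome. Of the macrophage acetylated regions, 48.6% overlapped an adipocyte one (48.1 to 49.1), and of the adipocyte regions 31.8% overlapped a macrophage one (31.4 to 32.2). Shifts gave 6.46% and 4.71% (permutation p = 0.001 for each). The base pairs acetylated in both cell types came to 29.96 Mb, 56.5% of the macrophage and 29.9% of the adipocyte total.

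Acetylation at PPARγ regions followed the cell type in which the receptor was bound. Macrophage-only regions were acetylated in macrophages in 56.6% of cases (54.3 to 58.9) and in adipocytes in 29.7% (27.6 to 31.9). Of them, 565 were acetylated in macrophages alone and 95 in adipocytes alone, exact McNemar p = 2.85e-82. Adipocyte-only regions were acetylated in adipocytes in 81.1% of cases (79.5 to 82.6) and in macrophages in 14.5% (13.1 to 15.9), with 1622 regions acetylated in adipocytes alone and 11 in macrophages alone. Shared regions were mostly acetylated in both cell types (140 of 214, 65.4%). In the shared class 37 regions were acetylated in adipocytes alone and 14 in macrophages alone, exact McNemar p = 0.00177. That difference, -10.7 percentage points in macrophages minus adipocytes, depended on the setting. It turned to 13.2 points with centres within 1000 bp, and with the combined adipocyte list it was -2.53 points with an exact p of 0.261. It kept its direction and passed the threshold in the other settings, and was -20.7 points with the longer macrophage list. The macrophage excess at macrophage-only regions was 26.9 percentage points and fell to 12.4 with the longer macrophage list, and the adipocyte excess at adipocyte-only regions shrank from a macrophage-minus-adipocyte difference of -66.6 to -42.1 points with centres within 1000 bp. Adipocyte H3K9Ace covers more of the genome, 100.1 Mb against 53.1 Mb. Shifted shared regions met it in 5.35% of cases, and macrophage H3K9Ace in 2.84%. The McNemar tests do not allow for this tilt toward adipocytes, and how much it adds to the adipocyte excesses was not tested.

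Between classes, adipocyte H3K9Ace showed no detectable difference of shared from adipocyte-only regions, with an odds ratio of 1.11 (0.766 to 1.66, Fisher's exact test, adjusted p = 0.648). Macrophage H3K9Ace was less frequent at macrophage-only than at shared regions, with an odds ratio of 0.508 (0.365 to 0.701, Fisher's exact test, adjusted p = 1.62e-05).

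The authors' fold per region was higher where other marks were present. In the macrophage list the median fold was 6.37 at the 1246 regions with PU.1 and 5.96 at the 715 without it, and 6.46 at the 1172 regions with C/EBPβ and 5.93 at the 789 without it (permutation, adjusted p = 1.5e-05 for each). Shared regions had a median of 7.81 in the macrophage list, against 6.12 at macrophage-only regions (permutation, adjusted p = 1.5e-05). In the adipocyte list shared regions had a median of 7.00 against 6.35 (permutation, adjusted p = 1.5e-05), and acetylated regions 6.47 against 6.10 (permutation, adjusted p = 6e-05). Macrophage H3K9Ace made no detectable difference to the macrophage median, 6.23 with and 6.14 without (permutation, adjusted p = 0.268), although the mean log2 fold differed by 0.049 (permutation, adjusted p = 0.0108). From the lowest to the highest quartile of macrophage fold, the share of regions with C/EBPβ was 51.5%, 53.3%, 60.4% and 73.9%, and that of regions shared with adipocytes 5.70%, 6.73%, 9.18% and 22.04%.

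The macrophage-only regions with the highest fold carried both macrophage factors in 7 of 8 cases. The highest, on chromosome 9 at 61135699 to 61136036 in mm8, had a fold of 23.3, C/EBPβ and macrophage H3K9Ace but no PU.1. The next, on chromosome 5 at 141266756 to 141267034 (fold 21.9), chromosome 18 at 4313904 to 4314445 (20.5) and chromosome 3 at 51297632 to 51298033 (20.4), had both factors. So did the regions on chromosome 10 at 66600257 to 66600642 (20.3), chromosome 19 at 34581704 to 34582155 (19.4), chromosome 12 at 86274439 to 86275334 (18.65) and chromosome 7 at 81722702 to 81723237 (18.5). Of these 8 regions 5 were acetylated in macrophages and 2 in adipocytes.

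Of the 8 shared regions with the highest macrophage fold, 7 carried C/EBPβ and 5 PU.1. Regions on chromosome 2 at 29594115 to 29594496 (fold 22.5), chromosome 4 at 86161263 to 86161787 (21.8) and chromosome 11 at 100819156 to 100819466 (20.97) had both factors and macrophage H3K9Ace, as the region on chromosome 6 at 125006689 to 125007004 (18.7) had both factors without it. C/EBPβ alone was found on chromosome 14 at 103222571 to 103222776 (22.1), chromosome 15 at 91007742 to 91008042 (19.8) and chromosome 2 at 144060182 to 144060462 (18.4). The region on chromosome 3 at 90339924 to 90340431 (18.05) had PU.1 without C/EBPβ. In each cell type 6 of the 8 were acetylated.

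The 8 adipocyte-only regions with the highest fold were all acetylated in adipocytes, and none carried macrophage PU.1. Chromosome 6, over-represented in the adipocyte lists, held those at 134567494 to 134567847 (fold 18.55), 140591970 to 140592207 (18.5), 5459714 to 5460166 (18.4), 52118682 to 52118996 (16.8), 30594058 to 30594395 (16.8) and 113404536 to 113404783 (16.5). The other two lay on chromosome 19 at 15971733 to 15972066 (18.25) and chromosome 2 at 163163182 to 163163526 (17.9). The latter was the only region of the 8 with C/EBPβ or H3K9Ace in macrophages.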

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

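All tests in this part were chosen after seeing the data. For the strata of height, width and acetylation in the final list, the bounds were written before the value of the test itself was seen. PU.1 and C/EBPβ moved in opposite directions between classes of the same list: from macrophage-only to shared regions the share with PU.1 fell and the share with C/EBPβ rose, so the change in C/EBPβ exceeded that in PU.1 by 29.4 percentage points (permutation p = 1e-05, the smallest the resamples can give). The odds ratio of PU.1, shared over macrophage-only, was 0.557 without strata. Within quartiles of peak height the common odds ratio was 0.350 (95% interval 0.256 to 0.478). It was 0.394 (0.289 to 0.536) within quartiles of region width and 0.477 (0.355 to 0.640) within strata of macrophage H3K9Ace. The PU.1 contrast was thus larger within each of these strata, and peak strength, width and acetylation do not account for it as a whole. For strength this could be foreseen, so that test had little chance of another outcome. Shared regions had higher peaks than macrophage-only regions (median 19 against 12). PU.1 was also more frequent at stronger macrophage regions, at 57.0% of the lowest and 73.5% of the highest quartile of fold. C/EBPβ had a ratio of 1.99 without strata and, within the same strata, 1.42 (1.02 to 1.98), 1.60 (1.15 to 2.21) and 1.73 (1.26 to 2.38). The C/EBPβ contrast was therefore smaller within strata, most of all those of peak height, so these traits may account for part of it. In the longer macrophage list the PU.1 contrast was reversed, and within strata of height in that list it was 0.706 (0.566 to 0.880), so its many weaker macrophage-only regions may produce the reversal. With the combined adipocyte list the PU.1 odds ratio of macrophage-only over shared regions shrank from 1.80 to 1.26. The PU.1 contrast was thus weak with that list, while the C/EBPβ ratio was 0.516 there, against 0.503 with the final lists. As a hypothesis raised by these data and not tested, positions bound by PPARγ in both cell types may rely less on PU.1. They may rely on factors that both cell types have, such as C/EBP proteins, but adipocyte C/EBP occupancy was not analysed here.

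The acetylation contrast also differed between classes: the odds of H3K9Ace in macrophages alone over adipocytes alone were 877 times higher at macrophage-only than at adipocyte-only PPARγ regions (Fisher's exact test, 95% interval 461.1 to 1813).

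Regions outside the main comparisons were looked at as well. The longer macrophage PPARγ list has 30 regions that pass the fold and false discovery rate limits but overlap masked intervals, which were subtracted as areas of input bias, and whether their folds reflect PPARγ was not tested. Among them, chosen after their values were seen, 9 lie within chromosome 6 from 72528080 to 72536955 with folds of 6.81 to 13.4, and 7 within chromosome 4 from 135444820 to 135465188 with folds of 5.09 to 9.03. Of the 16424 unmasked regions of that list outside the final list, 26.8% overlapped PU.1 (26.1 to 27.5), against 0.955% after shifting (permutation p = 0.001).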

How the results depend on the processing

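Leaving out chromosome 6 was chosen after seeing the data. Over 25 results and 138 alternative values, 134 kept their direction and their side of the threshold of 0.05. Alternatives that left a value exactly as it was are not counted there: all 25 with masked regions removed, as no region of the final lists overlapped them, and 8 others. Several counted values are not separate: classes that avoid both longer lists repeat values obtained with 1 of those lists. Most p-values were also far below the threshold or the smallest the shifts can give, so few could have crossed it. The longer macrophage list was used with its 85 masked regions. With the longer macrophage list the PU.1 odds ratio of macrophage-only over shared regions reversed to 0.559, and the values within strata of peak height given above bear on it. At shared regions the macrophage-minus-adipocyte difference in H3K9Ace reversed to 13.2 percentage points with centres within 1000 bp. That setting misses PPARγ regions that lie inside a wide acetylated region but far from its centre. Adipocytes had 745 acetylated regions of at least 10000 bp with 322 PPARγ regions inside, and macrophages 38 with 16. How much of the reversal this makes was not tested. With the combined adipocyte list the difference was -2.53, no longer past the threshold, for a cause that was not tested. The other settings that moved it gave -9.68 to -20.7. For macrophage PPARγ fold with against without macrophage H3K9Ace, the difference in mean log2 fold, 0.049, passed the threshold that the difference in medians missed, and the cause was not tested. The shared part was 2.07% of the longer macrophage PPARγ list and 28.2% of the final one set against the combined adipocyte list. These are shares of different lists. The first is held down by list length, with 18470 macrophage regions against 2634 adipocyte regions. The PU.1 odds ratio of macrophage-only over adipocyte-only regions ranged from 10.3 to 44.4 and that of C/EBPβ from 4.87 to 18.5. Gene lists near PPARγ regions, planned with windows of 50 kb and 10 kb, were not run. Depth is unknown, so a region missing from a list was not detected at that list's limits and is not shown to be unbound.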

Other observations

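All tests in this part were chosen after seeing the data. For the bins and dense clusters of chromosome 6 and for regions with neither factor by fold and distance, the bounds were written before the value of the test itself was seen, for patterns already noticed. Among PU.1 regions over the genome, macrophage acetylation went with C/EBPβ. H3K9Ace lay in macrophages at 56.5% of PU.1 regions with C/EBPβ (55.7 to 57.4) and at 34.5% of those without it (33.9 to 35.0), an odds ratio of 2.47 (2.37 to 2.58). In adipocytes, where PU.1 was not mapped here, the same positions differed less, 31.3% against 26.5% (odds ratio 1.26, 1.204 to 1.32, Fisher's exact test, p = 3.56e-24). C/EBPβ regions without PU.1 were acetylated in 44.0% of cases in macrophages and in 38.5% in adipocytes.

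PPARγ regions were denser in wide acetylated regions than in the narrowest ones. In adipocytes, H3K9Ace regions from 500 bp to under 1000 bp held 9.59 PPARγ regions per Mb (exact Poisson 95% interval 8.12 to 11.3) and those of at least 10000 bp held 29.0 per Mb (25.9 to 32.4), with 322 PPARγ regions in 745 such domains. Macrophages had 38 domains of that width with 16 PPARγ regions, 32.3 per Mb (18.5 to 52.5), against 13.8 per Mb (11.7 to 16.2) in the narrowest. The intermediate widths held 20.04 to 27.0 per Mb in macrophages and 21.5 to 24.2 per Mb in adipocytes, with no steady rise.

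Adipocyte lists had an excess of regions on chromosome 6. It held 14.2% of the final adipocyte PPARγ list and 9.36% of the combined one, against 6.94% of the final macrophage list. The PPARγ shares and odds ratios below use the final lists. Over the 19 autosomes the adipocyte to macrophage ratio of region shares went together for PPARγ and H3K9Ace, with Pearson's r = 0.858 (permutation p = 2e-05) and Spearman's rho = 0.763 (permutation p = 0.00028). Without chromosomes 5 and 6, the farthest from the median in the PPARγ ratio, r was 0.794. Dense clusters of PPARγ regions do not account for the excess on chromosome 6, as the odds ratio without its 3 densest 10-Mb bins was 2.44 (1.87 to 3.22). All 15 bins of the chromosome, 100% (exact 95% interval 78.2 to 100), had an adipocyte to macrophage ratio of H3K9Ace regions above the median of all autosomal bins. The H3K9Ace excess was thus spread along the chromosome, as a chromosome-wide cause such as extra copies in the 3T3-L1 line would give. The chromosome was picked for its excess in the same lists, so a high share of bins was likely beforehand and cannot decide on that cause. On chromosomes 8 and 15, 84.6% and 81.8% of the bins also lay above the median. Among H3K9Ace regions more than 50 kb from any adipocyte PPARγ region in both lists, the chromosome 6 odds ratio was 1.30 (1.16 to 1.46), which reaches below the bound of 1.2 set for a higher yield and leaves that open. A version that applied the distance to the adipocyte list alone gave 0.868 and is void, because it removes more of a chromosome dense in PPARγ. The median adipocyte fold showed no detectable difference, 6.46 on chromosome 6 and 6.38 elsewhere (permutation p = 0.448), but the mean log2 fold was 0.0582 higher there (permutation p = 0.0018), and 6 of the 8 adipocyte-only regions with the highest fold lie on it. From the lowest to the highest quartile of adipocyte fold, the chromosome held 13.1%, 14.3%, 13.1% and 16.5% of the regions. The odds ratio of the highest quartile over the rest was 1.27 (0.989 to 1.63), which missed the threshold (Fisher's exact test, p = 0.0535). A real preference of PPARγ for this chromosome in adipocytes was not tested.

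Macrophage-only PPARγ regions with neither PU.1 nor C/EBPβ made up 32.7% of the lowest quartile of fold and 8.70% of the highest (38 of 437, exact interval 6.23 to 11.7). Part of this group may therefore be weak or false regions. It includes the 14 macrophage PPARγ regions on chromosome Y, none of which overlapped PU.1 or C/EBPβ, whose lists hold only 5 and 4 regions there. Of the 394 regions, 31.0% (26.4 to 35.8) had a PU.1 or C/EBPβ centre within 1000 bp, against 3.91% after shifting (permutation p = 0.001). That lies below the bound of 50% set beforehand, so partners just beyond the region's edge do not account for most of the group. These regions were acetylated in macrophages in 36.5% of cases, against 62.5% with either factor (odds ratio 2.89, 2.27 to 3.67, Fisher's exact test, p = 9.05e-20), and in adipocytes in 25.9% against 30.8% (Fisher's exact test, p = 0.0605).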
